A study of Allium cepa with 12 samples.

How the data were processed

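Messenger RNA of 12 onion bulbs was sequenced after purification with poly-T beads, per the labels' protocols. Each library was assigned to its group (HW_HN, HW_LN, LW_HN or LW_LN) from its title, with 3 libraries in each of 4 groups. Replicate numbers run from 1 to 12 across the groups, so no number pairs bulbs. The design text says that bulbs were independent and taken at harvest, while the growth protocol speaks of time points and of plots. Neither the time point, the plot nor the sheath layer of a library is stated, and none entered a model. Whether the libraries kept strand information is left open by the protocol, so reads of overlapping or antisense genes cannot be told apart.

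The values are FPKM as deposited by the authors, one column per library, with a gene identifier, coordinates, a gene length and a description. The submitters' processing notes name fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 without saying what each was used for. The genome build was not given in the sources used here, and positions are printed as in the file. Gene lengths were multiples of 3 for 99.2% of models and are read as coding length. The deposited FPKM times the gene length gave whole multiples of one value per library for 100% of values above 0, within 0.02 of a read, so the reads behind each value were recovered. The library totals implied by these values differed from median-ratio size factors computed on the recovered reads by at most 0.0028%, so the deposited FPKM already carry such a scaling between libraries. Scaling by median ratios again therefore multiplied every library by one factor (1.0251) and tested nothing. How reads of near-identical copies were assigned is not given, so values of multigene families (peroxidases, heat shock proteins, lipid-transfer proteins, lachrymatory-factor synthases and others) and of gene models that are parts of one gene are uncertain.

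Depth was 25729258, 22632205 and 28302478 recovered reads in HW_HN 1 to 3, 35558147, 29702676 and 39152455 in HW_LN 4 to 6, 32905214, 27961830 and 23282256 in LW_HN 7 to 9, and 29874915, 27933220 and 26699432 in LW_LN 10 to 12. A gene without reads in all libraries of a group was given a floor of 3 reads per library, and a fold against it is written as a lower bound that covers counting error only.

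Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept, 44670 in all. Of these, 16594 carried a Swiss-Prot name, 2410 a Pfam family only and 25666 no description. A total of 13208 lay on chromosomes 1 to 8 and the rest on scaffolds. Log2(FPKM + 1) was fitted with group means for all 4 groups in limma 3.58.1 (R 4.3.3), with eBayes and a mean-variance trend, 8 residual degrees of freedom and a median of 12.6 after moderation. Differences are on that scale, which understates changes of low genes. An adjusted p printed for a gene is limma's with Benjamini-Hochberg adjustment over all genes tested in the comparison, or over the members of a list where the text says so, and the threshold was 0.05. The comparisons were sub-optimal against optimal nitrogen at each water level, sub-optimal against optimal water at each nitrogen level, and the interaction. An exact test of 3 libraries against 3 cannot go below 0.1. No count table was used here, and the count-based alternative was limma voom on the recovered reads.

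A total of 34 gene lists and the rule for naming genes were fixed before the data were examined. The lists were word patterns covering nutrient uptake, sulphur and flavour, sugars, secondary metabolism, water shortage, heat, defence, hormones, transcription factors, and markers of other tissues. A list meant for organelle-encoded genes, as a measure of RNA quality, also took in nuclear genes such as those of the beta subunit of mitochondrial ATP synthase, and is not read as such a measure. They were matched to the name of the similar protein or Pfam family. Exclusions of names caught by accident were written after the lists had first been tested, from names alone, and the uncleaned match to the whole description is one of the alternatives. A list for roots and suberised tissue had 1 measured member and was not tested, since at least 5 were required. That member, g414751, similar to Casparian strip membrane protein 1, measured 9.03 ± 0.937 FPKM in HW_HN, 14.5 ± 3.09 in HW_LN, 10.5 ± 6.47 in LW_HN and 10.9 ± 1.30 in LW_LN. The other 33 were tested with camera (preset correlation 0.01, two-sided) and adjusted over 165 tests, then again with an estimated correlation and with fry. With fry 0 of the 165 passed, either for movement one way or for change in either direction (smallest adjusted p = 0.997 and 0.879).

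The genes named were chosen by that rule. In each pairwise comparison it took up to 10 genes higher and 10 lower past the threshold, with an informative description and libraries that did not overlap. Where fewer than 5 passed it took the 5 with the smallest p, and for each list the members past the threshold or else the 1 with the smallest p. The rule did not say whether those 5 needed a description, so the 5 among all genes and the 5 among described genes were both taken, the second reading being added after values had been seen. Of these, the text gives those that matter most in full. Abundant genes in the closing section and g152702 in the interaction were chosen after their values were seen.

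The limma step was tested on simulated values for the 44670 genes before use, with 200 genes changed by a known amount in each of 5 runs, and made 4.8 false calls per run on average. Each simulated gene was drawn independently of the others. In the real data the correlations estimated for called lists lay between 0.032 and 0.228, so this count does not measure the false calls there. Camera was tested for nitrogen at optimal water on 200 simulated lists of 60 genes, drawn with each gene's residual spread over the 4 groups. Among lists with no shift and a correlation of 0.1 between genes, the preset correlation called 16% and the estimated one 0%. With a shift of 0.5 the preset correlation called 100% and the estimated one 81.5%. The lists of a run were then all shifted together and adjusted among themselves, so these 2 shares overstate the power where few lists are shifted. Alternatives tried were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, fits of only the compared groups, no trend, library weights, a minimum change of 1, voom, and leaving out each library. Leaving out a library covered the groups compared (all 12 libraries for the interaction). Leaving out libraries of the other groups, total-read scaling, leaving out HW_HN 1 and LW_HN 9 together, leaving out libraries from the list tests, and nitrogen and water differences averaged over the other factor were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.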

Results

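RNA was sequenced from 12 onion bulbs (*Allium cepa*, variety Matahari) taken from a field trial in which water and nitrogen fertiliser were each kept at an optimal or a sub-optimal level. The bulbs fell into 4 groups of 3. HW_HN had optimal water and nitrogen, HW_LN optimal water with sub-optimal nitrogen, LW_HN sub-optimal water with optimal nitrogen, and LW_LN sub-optimal supply of both. Each library came from a separate bulb, and all bulbs were inoculated with the bacterium *Salmonella enterica*, so that every comparison was between inoculated bulbs and none measured the inoculation itself. The tissue was described as outer and inner sheath, without saying which layer each library held. Expression was deposited as FPKM, fragments per kilobase of gene length scaled to the size of the library. The reads behind the values came to between 22632205 (HW_HN 2) and 39152455 (HW_LN 6) per library. Of 540896 gene models, 72011 were above 0 in at least 1 library and 44670 entered the tests. A description was attached to 42.5% of the tested models, as the name of a similar Swiss-Prot protein or a Pfam family, and names below stand for that similarity. Positions follow the file's own sequences, whose genome build was not given in the sources used here.

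The bulbs differed from one another about as much within groups as between them. Pearson correlations of log2(FPKM + 1) across genes lay between 0.933 and 0.949 among the HW_LN bulbs, between 0.86 and 0.917 in HW_HN, between 0.841 and 0.913 in LW_HN and between 0.888 and 0.927 in LW_LN. Between bulbs of different groups they lay between 0.853 and 0.942. The 4 groups took up 24.5% of the variance between libraries, against a median of 26.9% over other partitions of the 12 libraries into groups of 3 (exact permutation p = 0.759, one-sided, 15400 partitions). The first principal component held 25.6% of the variance. HW_HN 1 and LW_HN 9 lay at one end of it, with scores of -91.9 and -93.8, and LW_HN 7, LW_LN 10 and LW_HN 8 at the other, with 88.2, 70.2 and 69.1.

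**Figure D1:**
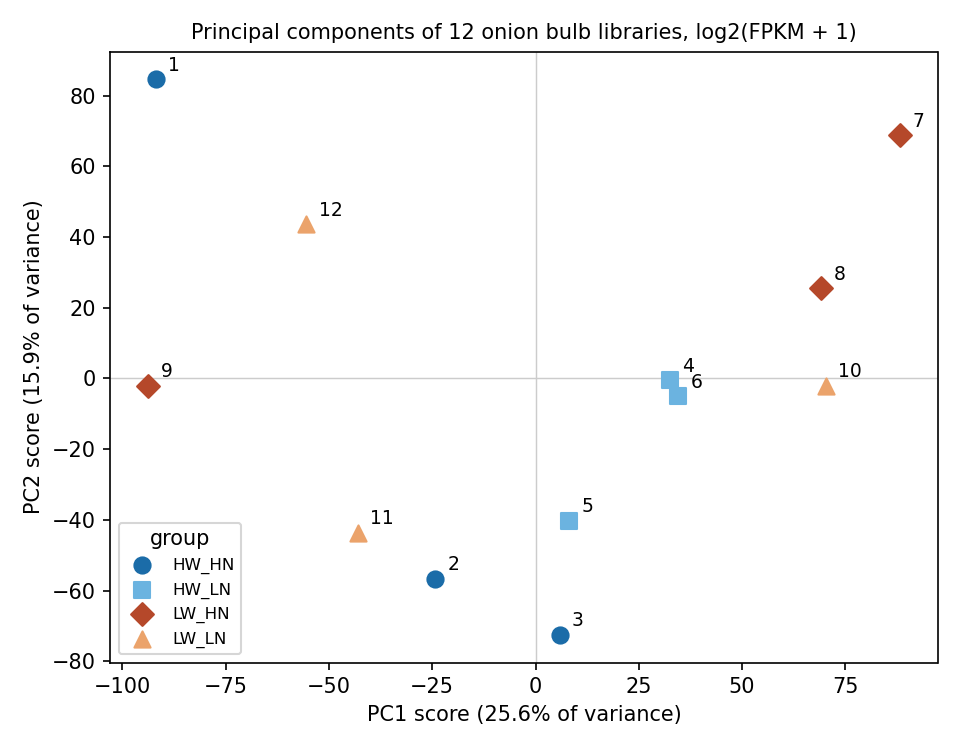
Scores of the 12 libraries on the first component (horizontal, 25.6% of variance) and the second component (vertical, 15.9% of variance) of log2(FPKM + 1), with colour and shape for the group and the replicate number beside each point. The HW_LN bulbs lie near one another, while HW_HN, LW_HN and LW_LN each spread over much of the first component.

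The first comparison named in the design text asked how sub-optimal nitrogen changed expression in bulbs grown with optimal water (HW_LN against HW_HN). All 3 HW_LN libraries held more recovered reads (at least 29702676) than the 3 HW_HN libraries (at most 28302478). Depth and nitrogen therefore went together in this comparison. The smallest p-values belonged to genes without a single recovered read in the 3 HW_HN bulbs. One was g427471, similar to ALE2, a receptor-like kinase that acts in epidermis formation in Arabidopsis, at 94257 to 97084 of Scaffold_79967-HRSCAF_463053. It stood at 7.96 ± 2.14 FPKM in HW_LN (SD, n = 3), at least 23.9-fold higher than a floor of 3 reads per library in HW_HN, with a log2 difference of 3.14 (SE 0.38, limma adjusted p = 0.06). On chromosome 8 the neighbours g149478 (26136949 to 26137735, no description) and g149477 (26136297 to 26136724), similar to DETOXIFICATION 26 of the MATE efflux carriers, stood at 5.32 ± 1.13 and 3.07 ± 0.00689 FPKM in HW_LN. These were at least 12.7-fold and 5.82-fold above the HW_HN floor, with limma adjusted p = 0.06 and 0.109. Lower in HW_LN was g19481, similar to the protein-folding enzyme PDIL2-2 (chromosome 2, 120394833 to 120398118), at 0.361 ± 0.159 FPKM against 6.88 ± 2.42 (limma adjusted p = 0.557).

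None of the 44670 genes passed limma's test at an adjusted p of 0.05 in this comparison. At an unadjusted p under 0.05 there were 1719 genes where 2234 would be expected with no effect, and limma voom on the recovered reads also called 0 genes (1449 unadjusted). Among the genes of nitrogen supply, 33 of 64 members of the nitrate and ammonium uptake list had a positive difference, with a median of 0.02 (camera adjusted p = 0.959). The member with the smallest p was g62696, similar to the peptide and nitrate transporter family protein NPF8.3, at 1.72 ± 0.687 FPKM in HW_LN and 0.63 ± 0.462 in HW_HN. The 36 genes of nitrogen assimilation had a median of -0.06 (camera adjusted p = 0.82), and g410513, a glutamate dehydrogenase-like gene, stood at 2.99 ± 0.932 against 7.05 ± 2.26 FPKM. For sulphur uptake and cysteine synthesis the median was 0.10 over 45 genes (adjusted p = 0.739), and for the flavour and thiosulfinate pathway -0.06 over 45 genes (adjusted p = 0.888). In the latter, g535061, similar to lachrymatory-factor synthase, which makes the tear-inducing compound of onion, measured 12.1 ± 9.94 FPKM in HW_LN and 0.59 ± 0.763 in HW_HN. Its log2 difference was 2.84 (limma adjusted p = 0.993). Fructan and sucrose metabolism had a median of -0.04 over 38 genes (adjusted p = 0.957), with g527501, similar to beta-fructofuranosidase 1, at 396 ± 148 against 131 ± 77.6 FPKM. Sugar transport and starch had a median of 0.10 over 63 genes (adjusted p = 0.683), with g33618, similar to the vacuolar sugar carrier MSSP2, at 88.6 ± 9.66 against 58.5 ± 12.7 FPKM.

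Camera with its preset correlation of 0.01 placed 6 lists apart from the other genes at this nitrogen contrast, and none of the 6 calls held with an estimated correlation (adjusted p = 0.976 for each). HW_HN 1 weighed on them. Without it the heat shock, peroxidase and WRKY lists were no longer called, and its mean for the heat shock list lay 0.57 above the mean of all libraries, against 0.12 and -0.19 for HW_HN 2 and HW_HN 3. The WRKY call also ended without HW_LN 6, the photosynthetic call without HW_LN 4, and the transposable element call without HW_HN 2 or HW_HN 3. With 1 library left out the medians ran from -0.34 to -0.04 for heat shock, 0.28 to 0.69 for peroxidases, 0.24 to 0.62 for WRKY factors, 0.23 to 0.36 for photosynthetic markers and -0.26 to -0.10 for transposable elements. The ribosomal call was kept without each of the 12 libraries, though only those of HW_HN and HW_LN can move its median. That median ran from 0.12 to 0.27 (the latter without HW_LN 4) and was 0.10 with quantile normalization. Class III peroxidases had the widest median of the 6 lists, 0.47, with 23 of 31 members positive (adjusted p = 0.00302), and g199259, similar to Peroxidase 42, stood at 24.7 ± 12.2 against 11.7 ± 4.16 FPKM. WRKY transcription factors, which act in defence, had a median of 0.35 with 23 of 28 positive (adjusted p = 0.016), and the WRKY51-like g515706 measured 23.8 ± 15.5 against 6.04 ± 4.92 FPKM. Cytosolic ribosomal proteins had a median of 0.17, with 224 of 282 positive (adjusted p = 0.00025). Heat shock proteins and chaperones had a median of -0.21, with 101 of 288 positive (adjusted p = 0.00113), though the DnaJ-like chaperone g315490 was higher in HW_LN, at 4.79 ± 0.14 against 0.955 ± 0.851 FPKM. Genes annotated as transposable elements had a median of -0.18, with 119 of 375 positive (adjusted p = 0.00288). Markers of photosynthetic cells stood apart as well, with a median of 0.25 and 43 of 63 positive (adjusted p = 0.00025), and the light-harvesting gene g79760, similar to CP26, measured 5.50 ± 4.94 against 0.0467 ± 0.0808 FPKM. No list member passed over all genes tested or adjusted over the list alone. The nearest was g60152 of the NAC transcription factors, at 2.79 ± 0.463 against 14.2 ± 5.23 FPKM, with a limma p of 0.0553 adjusted over the list alone. Without LW_HN 7, a library outside this comparison that enters through the shared spread, 4 genes passed limma's threshold, among them g427471 and g149478. Without HW_HN 1 and HW_HN 3, each left out in turn, 2 and 1 genes passed.

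The second named comparison asked the same question in bulbs grown with sub-optimal water (LW_LN against LW_HN). The ALE2-like g427471 was again higher at sub-optimal nitrogen, at 4.67 ± 0.737 against 0.51 ± 0.883 FPKM, with a log2 difference of 2.05 (SE 0.38, limma adjusted p = 1). The undescribed g81844 was without reads in the 3 LW_LN bulbs and stood at 7.40 ± 2.40 FPKM in LW_HN, at least 19.9-fold above the LW_LN floor (limma adjusted p = 0.734). Another undescribed gene, g242115, measured 24.5 ± 6.27 FPKM in LW_LN and 3.68 ± 1.63 in LW_HN (limma adjusted p = 0.734). Among described genes, g57151, similar to tubulin-folding cofactor B, which helps to assemble microtubules, stood at 39.6 ± 5.45 against 18.1 ± 2.35 FPKM. The GATA22-like transcription factor g113541 (chromosome 2, 275625548 to 275626753) measured 13.2 ± 7.75 against 1.60 ± 1.67 FPKM. Lower in LW_LN was g297222, similar to nicotinate N-methyltransferase 1, at 0.461 ± 0.163 against 3.09 ± 0.968 FPKM.

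Limma again called 0 of 44670 genes, with 1238 at an unadjusted p under 0.05, and voom called 0 (1098 unadjusted). The nitrate and ammonium uptake list had a median of 0.03 (camera adjusted p = 0.819) and nitrogen assimilation -0.06 (adjusted p = 0.831). In the flavour pathway, whose median was 0.02 (adjusted p = 0.997), g415874, similar to alliin lyase, the enzyme that splits the sulphur compounds of onion on wounding, measured 5.45 ± 4.63 FPKM in LW_LN and 17.6 ± 10.2 in LW_HN. Its log2 difference was -1.67 with an SE of 0.53. Fructan and sucrose metabolism had a median of -0.15 with 11 of 38 members positive (adjusted p = 0.187). The pathogenesis-related and antimicrobial list had a median of -0.10 over 126 genes (adjusted p = 0.0862), and its PR1-like g137764 stood at 0.551 ± 0.345 against 8.51 ± 8.02 FPKM. Flavonoid and anthocyanin synthesis had a median of -0.38 with 9 of 36 members positive (adjusted p = 0.244).

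Of the lists, 6 stood apart at this contrast with the preset correlation, and none of the 6 calls held with an estimated correlation (adjusted p = 0.976 for each). Each call also ended with some single library left out, and bulbs of the 2 groups lay among one another. In the jasmonate list LW_HN 9 (-0.50) lay with LW_LN 11 and LW_LN 12 (-0.36 and -0.26), and LW_LN 10 (0.61) with LW_HN 7 and LW_HN 8 (0.63 and 0.87), as distances of a bulb's mean from that of all libraries. The phenylpropanoid and jasmonate calls ended without LW_HN 7, LW_HN 8, LW_LN 11 or LW_LN 12, and the cuticle call without LW_HN 8, LW_HN 9, LW_LN 11 or LW_LN 12. The phosphate and iron call ended without LW_HN 8 or LW_LN 11, that of dividing cells without LW_LN 11, and that of transposable elements without LW_HN 7, LW_LN 10 or LW_LN 11. In the same order the medians ran from -0.40 to -0.09, -0.37 to -0.04, -0.33 to -0.02, -0.30 to -0.05, 0.08 to 0.25 and 0.01 to 0.25. Phenylpropanoid and lignin genes had a median of -0.27 with 26 of 79 positive (adjusted p = 0.0268), although the caffeic acid O-methyltransferase-like g528853 was higher in LW_LN, by 1.09 on the log2 scale (SE 0.38). Cuticle, wax and suberin genes had a median of -0.17 with 40 of 125 positive (adjusted p = 0.013), among them the KCS6-like wax synthesis gene g449418 at 6.88 ± 1.08 against 12.4 ± 2.40 FPKM. Jasmonate and lipoxygenase genes had a median of -0.27 with 19 of 69 positive (adjusted p = 0.0284), and phosphate and iron genes -0.19 with 24 of 87 positive (adjusted p = 0.00367). The vacuolar iron transporter-like g223553 measured 0.924 ± 0.355 against 3.81 ± 2.57 FPKM. Markers of dividing cells had a median of 0.18 with 268 of 383 positive (adjusted p = 0.0032), with the cyclin B1-5-like g286906 at 2.29 ± 1.39 against 0.35 ± 0.312 FPKM. Transposable element annotations had a median of 0.14 with 268 of 375 positive (adjusted p = 0.00255). No member passed over all genes tested or adjusted over the list alone. Leaving out LW_HN 9 gave 4 genes past the threshold, and leaving out LW_HN 7, LW_HN 8 or HW_LN 5 gave 1 each, which was g81844 without HW_LN 5.

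The layout of the trial also gave 2 comparisons of water supply, which the design text did not name. At optimal nitrogen (LW_HN against HW_HN) the chromosome 8 neighbours g149478 and g149477, without reads in HW_HN, stood at 6.17 ± 1.39 and 2.91 ± 0.677 FPKM in LW_HN. They were at least 14.7-fold and 5.53-fold above the HW_HN floor (limma adjusted p = 0.0592 and 0.157). The HW_HN bulbs without reads are the same as in the first nitrogen comparison, so this is not separate evidence. Whether these neighbours are parts of one gene was not tested. A pair of neighbours on Scaffold_63197-HRSCAF_446283 was lower at sub-optimal water. The undescribed g292339 (173352 to 176662) measured 0.865 ± 0.279 against 9.66 ± 1.54 FPKM, a log2 difference of -2.52 (SE 0.34, limma adjusted p = 0.118), and g292340 (176861 to 180820), similar to the RNA-binding protein LARP6B, measured 1.72 ± 1.08 against 8.10 ± 3.09 FPKM. The acyl-CoA thioesterase-like g477400 stood at 16.0 ± 1.43 against 57.0 ± 3.33 FPKM, with every LW_HN bulb below every HW_HN bulb (limma adjusted p = 0.412).

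Limma called 0 genes for water at optimal nitrogen, with 1878 at an unadjusted p under 0.05, and voom called 0 (1430 unadjusted). Lists of water shortage did not stand apart. Abscisic acid genes had a median of -0.17 over 21 genes (camera adjusted p = 0.597), dehydrins, LEA proteins and osmoprotection -0.03 over 70 genes (adjusted p = 0.819), and aquaporins 0.18 over 39 genes (adjusted p = 0.463). The ABA receptor-like g414760, similar to PYL4, differed by -0.51 on the log2 scale (SE 0.30), and the PIP2-1-like water channel g508071 measured 1.46 ± 0.57 against 0.252 ± 0.22 FPKM. Fructan and sucrose metabolism had a median of 0.09 (adjusted p = 0.0604), with the fructosyltransferase-like g13635 at 6.78 ± 6.12 against 0.0104 ± 0.0179 FPKM. Nitrogen assimilation had a median of 0.18 over 36 genes (adjusted p = 0.318), and the glutamine synthetase-like g279697 measured 42.1 ± 10.6 against 25.3 ± 1.58 FPKM. The gamma-thionin family gene g375231, of a class of small antimicrobial peptides, stood at 169 ± 51.8 against 508 ± 129 FPKM, in a list whose median was 0.05 over 126 genes (adjusted p = 0.296).

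With the preset correlation 7 lists stood apart for water at optimal nitrogen. With an estimated correlation none of them did (adjusted p = 0.987 for the photosynthetic list and 0.976 for the other 6). All 7 calls ended with some single library left out. Leaving out LW_HN 8 ended all but the transposable element call, and HW_HN 1 those of phenylpropanoid, heat shock, peroxidase and phosphate and iron genes. LW_HN 7 ended those of phenylpropanoid genes, peroxidases and transposable elements, and HW_HN 3 those of peroxidases, phosphate and iron genes, photosynthetic markers and transposable elements. The last also ended without HW_HN 2, the photosynthetic call without LW_HN 9, LW_LN 10, LW_LN 11 or LW_LN 12, and the peroxidase call without LW_LN 11 or LW_LN 12. The LW_LN libraries lie outside this comparison and left these medians unchanged, at 0.26 and 0.33. They enter through the shared spread and through the adjustment over 165 tests. With 1 library left out the medians ran from 0.27 to 0.63 for jasmonate, 0.15 to 0.41 for phenylpropanoid, 0.09 to 0.68 for peroxidase, 0.06 to 0.23 for phosphate and iron, -0.26 to 0 for heat shock, -0.28 to -0.03 for transposable element and 0.07 to 0.35 for photosynthetic genes. Jasmonate and lipoxygenase genes had a median of 0.44 with 49 of 69 positive (adjusted p = 0.00025), with the jasmonate repressor-like g325857, similar to TIFY 6B, at 33.8 ± 14.6 against 17.1 ± 1.57 FPKM. Phenylpropanoid and lignin genes had a median of 0.37 with 53 of 79 positive (adjusted p = 0.00298), among them the caffeic acid O-methyltransferase-like g154507 at 161 ± 112 against 24.4 ± 20.4 FPKM. Class III peroxidases had a median of 0.33 with 24 of 31 positive (adjusted p = 0.0313), with the Peroxidase 5-like g176598 at 80.9 ± 100 against 0.234 ± 0.307 FPKM. Phosphate and iron genes had a median of 0.12 with 58 of 87 positive (adjusted p = 0.0114). Heat shock proteins and chaperones had a median of -0.18 with 101 of 288 positive (adjusted p = 0.00693), and the chloroplast small heat shock gene g65687 measured 16.3 ± 6.08 against 39.4 ± 19.5 FPKM. Transposable element annotations had a median of -0.14 (adjusted p = 0.00352). Photosynthetic markers stood apart as well, with a median of 0.26 and 44 of 63 positive (adjusted p = 0.0467). No member passed over all genes tested or adjusted over the list alone. LW_HN 9 weighed on this comparison, since 46 genes passed without it, 43 of them higher in LW_HN. Without HW_HN 1 and LW_HN 7, each left out in turn, 3 and 2 genes passed, and 1 gene passed without LW_HN 8, HW_HN 3, HW_LN 5 or LW_LN 11.

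At sub-optimal nitrogen (LW_LN against HW_LN) the lowest p-value belonged to g168347, without a description, at 12.5 ± 1.78 FPKM in HW_LN and without reads in LW_LN. It was at least 43-fold higher in HW_LN than the LW_LN floor, with a log2 difference of -3.74 (SE 0.49, limma adjusted p = 0.195). The neighbours g292339 and g292340 were lower in LW_LN, at 0.898 ± 0.678 against 6.95 ± 0.807 FPKM and at 1.03 ± 0.446 against 6.36 ± 0.624 FPKM. The aquaporin-like g422990, similar to PIP2-6, stood at 2.78 ± 2.76 against 17.1 ± 4.10 FPKM (log2 difference -2.59, SE 0.65, limma adjusted p = 1). The telomere-binding protein-like g294974 (chromosome 1, 27030897 to 27032729) measured 0.688 ± 0.347 against 5.81 ± 0.44 FPKM. Higher in LW_LN was g339189 (chromosome 5, 20037664 to 20039050), similar to chloroplast glucose-6-phosphate dehydrogenase, which supplies reducing power, at 5.84 ± 0.659 against 2.08 ± 0.99 FPKM.

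Limma called 0 genes for water at sub-optimal nitrogen, with 1319 at an unadjusted p under 0.05, and voom called 0 (1214 unadjusted). Abscisic acid genes had a median of 0.01 (camera adjusted p = 0.992), and the dehydrin and LEA list 0.02 (adjusted p = 0.957). Its trehalose-phosphate synthase-like g152702 stood at 36.7 ± 11.8 against 16.2 ± 4.08 FPKM. Aquaporins as a list had a median of -0.02 (adjusted p = 0.762). The nitrate transporter family gene g30191, similar to NPF2.11, measured 3.35 ± 1.02 against 1.24 ± 0.707 FPKM, in a list with a median of 0.05 (adjusted p = 0.485). Sulphur uptake and cysteine synthesis had a median of 0.01 (adjusted p = 0.874), with the cysteine synthase-like g338392 at 33.9 ± 14.2 against 13.1 ± 3.17 FPKM. Expansins and cell wall remodelling had a median of -0.12 over 247 genes (adjusted p = 0.147), and g270533, similar to the xyloglucan-modifying enzyme XTH15, measured 7.95 ± 6.33 against 76.3 ± 56.4 FPKM.

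With the preset correlation 5 lists stood apart for water at sub-optimal nitrogen, and no call held with an estimated correlation (adjusted p = 0.976 for each). The ribosomal call was kept without each of the 12 libraries, though only those of HW_LN and LW_LN can move its median. That median ran from -0.36 to -0.20 and was -0.17 with quantile normalization. The cuticle and peroxidase calls ended without HW_LN 6, LW_LN 11 or LW_LN 12, the transposable element call without LW_LN 10 or LW_LN 11, and the photosynthetic call without HW_LN 4. In that order the medians of these 4 ran from -0.30 to -0.11, -0.48 to -0.26, 0.09 to 0.21 and -0.50 to -0.20, the photosynthetic median being -0.20 without LW_LN 10. Cytosolic ribosomal proteins had a median of -0.27, with 36 of 282 positive (adjusted p = 5.54e-12), and the L35a-like g488938 stood at 27.8 ± 6.21 against 67.9 ± 24.4 FPKM. Class III peroxidases had a median of -0.39 with 8 of 31 positive (adjusted p = 0.00537), and the Peroxidase 4-like g134325 measured 6.30 ± 4.41 against 19.4 ± 2.36 FPKM. Cuticle, wax and suberin genes had a median of -0.20 with 45 of 125 positive (adjusted p = 0.0252). Transposable element annotations had a median of 0.15 with 262 of 375 positive (adjusted p = 0.00249). Photosynthetic markers also stood apart, at a median of -0.42 with 16 of 63 positive (adjusted p = 6e-04), with the photosystem I gene g258030 at 0.887 ± 0.396 against 2.09 ± 0.981 FPKM. No member passed over all genes tested or adjusted over the list alone. Without LW_HN 7, a library outside this comparison, 3 genes passed limma's threshold, among them g168347, and without HW_HN 1 there was 1.

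**Figure D2:**
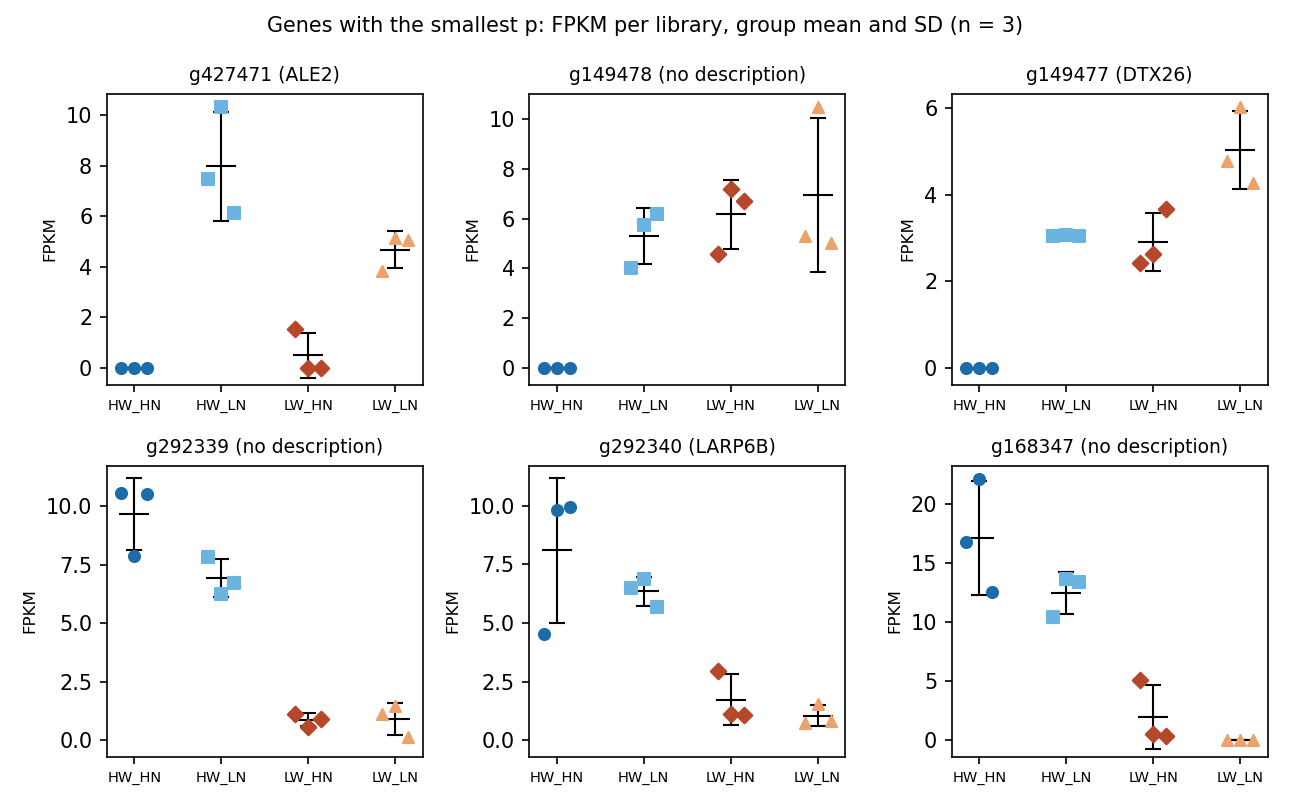
FPKM (vertical, linear scale) of 6 genes with small p-values in each library, with horizontal bars for the group mean and error bars for the SD (n = 3). Genes g427471, g149478 and g149477 lie at 0 in all 3 HW_HN bulbs, and g292339, g292340 and g168347 lie lower in both groups with sub-optimal water than in both with optimal water.

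The interaction asked whether the nitrogen difference itself depended on water supply. Limma called 0 genes, with 1772 at an unadjusted p under 0.05, and voom called 0 (1694 unadjusted). The gene that stood out within a list was g152702 (chromosome 8, 102005893 to 102006093), similar to TPS5 of the trehalose-phosphate synthases, a short gene model that may be a fragment. It measured 36.7 ± 10.6 FPKM in HW_HN, 16.2 ± 4.08 in HW_LN, 14.1 ± 7.59 in LW_HN and 36.7 ± 11.8 in LW_LN. Its interaction on the log2 scale was 2.50 (SE 0.52), with a limma p of 0.0252 adjusted over the list alone and 0.982 adjusted over all genes tested. It was the only member to pass in 165 adjustments over a list alone. Among the lists, 7 stood apart with the preset correlation and none with an estimated one (adjusted p = 0.976 for each of the 7). Class III peroxidases had a median interaction of -0.76, with 7 of 31 members positive, and photosynthetic markers -0.43, with 13 of 63 positive. Cuticle, wax and suberin genes had a median of -0.39, phenylpropanoid and lignin genes -0.35, ribosomal proteins -0.26 and phosphate and iron genes -0.24, while transposable element annotations had a median of 0.32. With 1 library left out the peroxidase median ran from -1.11 to -0.61, the photosynthetic one from -0.74 (without LW_HN 7) to -0.31, the ribosomal one from -0.39 (without LW_HN 9) to -0.15 (without LW_HN 7) and the transposable element one from 0.19 (without LW_HN 7) to 0.44, and these 4 calls were kept. Quantile normalization gave -0.15 for ribosomal proteins and -0.14 for phosphate and iron genes. The cuticle and phenylpropanoid calls ended without HW_HN 1 or LW_HN 8 (medians from -0.51 to -0.16 and from -0.47 to -0.28). The phosphate and iron call ended without HW_HN 1, HW_HN 3, HW_LN 4, LW_HN 8 or LW_LN 11 (-0.32 to -0.12). Lists for oxidative stress, immune receptors, ethylene, auxin, gibberellin and cytokinin, MYB, NAC and bHLH, bZIP and MADS factors, proteases and organelle proteins were not called in any of the 5 comparisons. The lowest adjusted p among them was 0.0834, for gibberellin and cytokinin genes and nitrogen at sub-optimal water (median 0.14 over 38 genes). Leaving out HW_HN 3 gave 1 gene past the threshold.

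**Figure D3:**
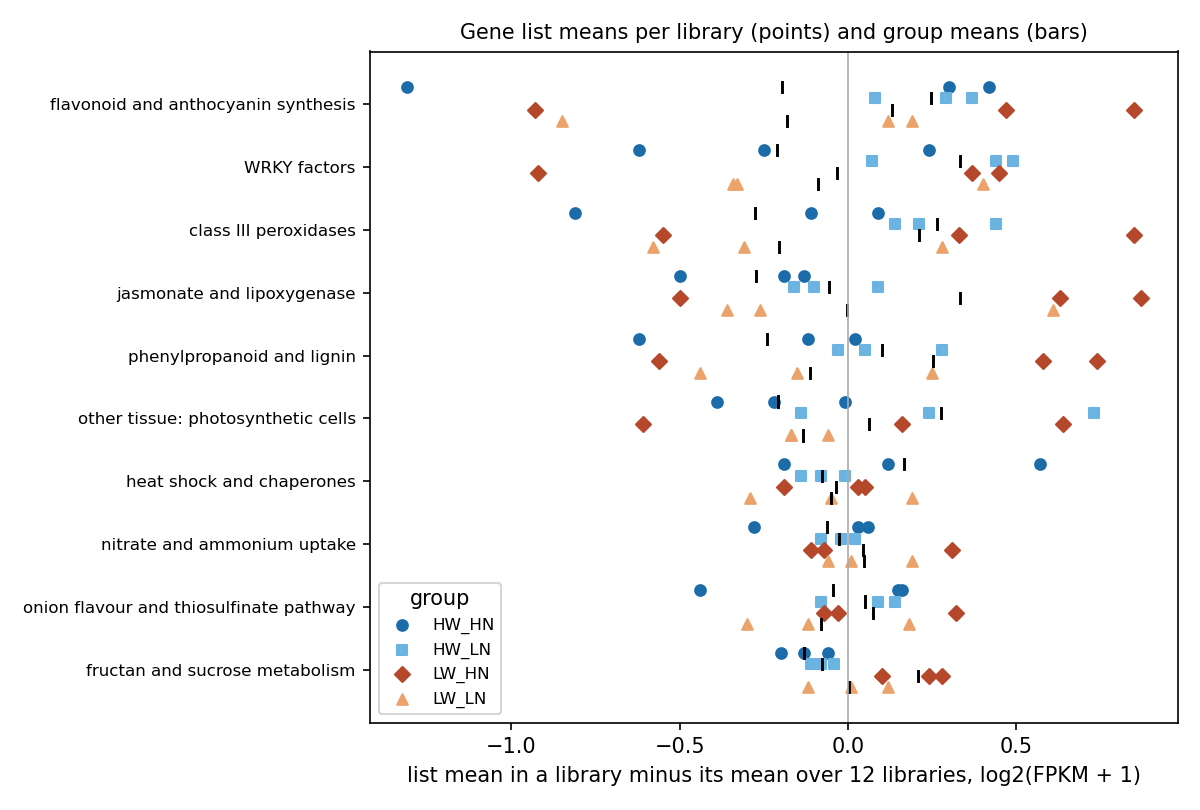
Mean of a list's genes in each library minus that list's mean over the 12 libraries (horizontal, log2(FPKM + 1)) for 10 gene lists (vertical), with points for libraries and vertical bars for group means. Bulbs of one group lie far apart in the flavonoid, WRKY and peroxidase lists, and closer together in the fructan list.

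The precision of these comparisons was set by the spread between bulbs. The median standard error of a pairwise log2 difference was 0.39 and its 95% interval reached 0.85 to either side, against 0.55 and 1.2 for the interaction. In data simulated with each gene's residual spread over the 4 groups, the test of nitrogen at optimal water recovered 3.2% of genes changed by 1 on the log2 scale. It recovered 44% at 2, 79.2% at 3 and 90.8% at 4. These shares overstate the recovery of a lone changed gene, because 200 genes changed together eases the adjustment. Simulated genes also varied independently of one another, and their values could fall below 0, which log2(FPKM + 1) cannot. A lone gene with the median standard error would need a difference of 3.41, or 4.82 for the interaction. Genes whose 3 libraries of one group all lay above the 3 of the other made up 12.5% for nitrogen at optimal water, 5.5% for nitrogen at sub-optimal water, 6.1% for water at optimal nitrogen and 10% for water at sub-optimal nitrogen, where chance gives 10%.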

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

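The tests of correlation within lists, of the groups along the first component and of a label exchange were chosen only after the result was seen. The counts of other groupings and the thinning test were set before their results were seen. So was the scaling test, although total-read scaling itself was chosen after the data were seen.

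In camera's test of the interaction, whether the nitrogen difference depends on water supply, 7 lists passed with the preset correlation and none of them with an estimated one (adjusted p = 0.976 for each). With the preset correlation the adjusted p was 6.73e-05 for transposable element annotations, 0.000205 for cytosolic ribosomal proteins, 0.00025 for photosynthetic markers, 0.000644 for class III peroxidases, 0.00367 for phenylpropanoid and lignin genes, 0.00482 for cuticle, wax and suberin genes and 0.0381 for phosphate and iron genes. The interaction of g152702, similar to trehalose-phosphate synthase 5, also passed with a limma p of 0.0252 adjusted over its list alone, and not over all genes tested (0.982). Adjustment over a list alone was made 165 times, for each list and comparison, and 1 member passed in all. Chance cannot be excluded for it.

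The lists called with the preset correlation numbered 31 of 165. Chance cannot be excluded, because 39 of 100 groupings of the 12 libraries, the real one included, called as many, with a highest other count of 57. For the interaction alone 35 of 100 groupings called as many as 7. Of the 31 calls, 0 held with correlations estimated from the data, which lay between 0.032 and 0.228 for the called lists against the preset 0.01, so genes of a list that vary together from bulb to bulb are a candidate explanation. A dependence of these pathways on water and nitrogen stays open. In simulated lists with a correlation of 0.1 the test of nitrogen at optimal water with an estimated correlation found 81.5% of shifts of 0.5. All lists of a simulated run were shifted together and adjusted among themselves, so this share overstates the power where few of 165 tests hold a shift. Smaller shifts, higher correlations and the interaction were not simulated. By median, only the peroxidase interaction (-0.76) among the called lists was larger than 0.5 in size. By mean, which is closer to the simulated shift of every member, further calls were larger. These were peroxidases and WRKY factors (0.54 each) for nitrogen at optimal water and jasmonate genes (0.60) for water at optimal nitrogen. The phenylpropanoid (-0.71) and photosynthetic (-0.68) interactions were larger too.

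Bulbs of one group lay far apart along the first principal component, and in the 10 splits of the 6 libraries with sub-optimal water the one that set LW_HN 7, LW_HN 8 and LW_LN 10 against LW_HN 9, LW_LN 11 and LW_LN 12 called 1759 genes where the real nitrogen split called 0, which points to a structure among these bulbs that the labels do not give. The tables argue against the number of reads as its cause, since thinning every library to the depth of the smallest, which took up to 42.2% of a library's reads and set 948 values to 0, moved no score by more than 0.37 of a range of 182 (correlation of 0.9999956), and against the choice between median-ratio and total-read scaling alone, which is too small, with factors between 0.95 and 1.13 that moved no score by more than 2.6 (correlation of 0.9997). Scores still went with recovered reads over the 12 libraries (Pearson's r = 0.63, permutation p = 0.0291; Spearman's rho = 0.78, permutation p = 0.00436; r = 0.76 without HW_LN 6 and HW_LN 4; 1 relation computed), so RNA yield or quality that goes with depth stays open and was not tested. The groups may contribute, as the exact permutation p of 0.626 for their share of the scores excludes nothing. An exchange of the labels of LW_HN 9 and LW_LN 10 cannot be told apart from variation between bulbs, because the scores would look the same under either. The test of it counted libraries with optimal water at the same end, where 1, HW_HN 1, lay. That count cannot decide it either way. Sheath layer, plot and time point are not stated for any library.

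For nitrogen at optimal water, nitrogen at sub-optimal water, water at optimal nitrogen and water at sub-optimal nitrogen, the 6 libraries make 10 splits, too few for a share under 0.05. The real count was 0 in each, and the highest other counts were 6, 1759, 8 and 4. For the interaction the real count was also 0, so that all 100 of 100 groupings had to reach it and the count decides nothing. The highest other count, 545, points to a structure among the libraries as well.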

How the results depend on the processing

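Total-read scaling, leaving out HW_HN 1 and LW_HN 9 together, leaving out libraries outside a comparison or from the list tests, and both averaged differences were chosen after the data were seen. Order below is nitrogen at optimal water, nitrogen at sub-optimal water, water at optimal nitrogen, water at sub-optimal nitrogen and the interaction, each with 0 genes in the reported limma fit. Each stayed at 0 with the filter of 5 FPKM, quantile normalization, a minimum change of 1, voom and total-read scaling, and median-ratio scaling changed no relative value. The counts were 3, 0, 3, 1 and 1 with a pseudocount of 0.1, and 0, 5, 6, 2 and 0 without a filter. They were 3, 0, 3, 0 and 0 without the trend, and 3, 0, 0, 1 and 0 with library weights. The 4 pairwise counts were 2, 0, 0 and 2 in fits of only the compared groups. Without HW_HN 1 and LW_HN 9 they were 2, 0, 14, 1 and 0. Leaving out 1 library gave 0 to 4 genes for nitrogen at optimal water (4 without LW_HN 7, 2 without HW_HN 1, 1 without HW_HN 3), 0 to 4 for nitrogen at sub-optimal water (4 without LW_HN 9, 1 without LW_HN 7, LW_HN 8 or HW_LN 5), 0 to 46 for water at optimal nitrogen (46 without LW_HN 9, 3 without HW_HN 1, 2 without LW_HN 7, 1 without HW_HN 3, LW_HN 8, HW_LN 5 or LW_LN 11), 0 to 3 for water at sub-optimal nitrogen (3 without LW_HN 7, 1 without HW_HN 1), and 0 to 1 for the interaction (1 without HW_HN 3). For genes, a library outside a comparison changes only the spread shared by all groups. For lists it also changes the adjustment, which runs over all 165 tests. A group with 1 library left out holds 2 bulbs, assumed to vary like the other groups.

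The averaged nitrogen difference called 1 gene, against 2 with a pseudocount of 0.1 (g149478 and g149477, with g427471 no longer called), 0 without a filter, 0 with the filter of 5 FPKM, 0 with voom and 0 to 7 without 1 library (7 without LW_HN 7, 3 without HW_HN 1, 2 without HW_HN 3, LW_HN 8 or LW_HN 9, and 0 without HW_HN 2, HW_LN 4, 5 or 6, or LW_LN 10, 11 or 12). The averaged water difference called 2 genes, against 3 with a pseudocount of 0.1 (g168347, g149478 and g149477, with g292339 no longer called), 3 without a filter, 5 with library weights, 0 with voom, 0 without HW_HN 1 and LW_HN 9, and 2 to 9 without 1 library (9 without LW_HN 7, 6 without HW_HN 1). The gene list calls, 31 with the preset correlation, came to 0 with an estimated correlation, 11 without a filter, 31 with lists by whole description, 35 with total-read scaling, 35 without HW_HN 1 and LW_HN 9, and 18 to 48 without 1 library (18 without LW_HN 8, 20 without LW_LN 11, 48 without LW_HN 9). Of the 31, 6 were kept without each of the 12 libraries and 25 ended without at least 1 of them. Of 4095 values of named genes under the alternatives, 4088 kept their sign and 47 came past the threshold. Many of these values could not change sign, so the 4088 overstate how stable the differences are. The filters, the trend, fits of only the compared groups and leaving out a library outside a pairwise comparison do not alter a difference. Median-ratio scaling barely does, and most of the genes were chosen for a small p. The sign changes were all in g414751. Its water difference at optimal nitrogen, 0.004, was -0.025 with a pseudocount of 0.1, -0.009 with quantile normalization and ran from -0.399 (without LW_HN 7) to 0.557 (without LW_HN 9) with 1 library left out, being below 0 also without LW_HN 8 (-0.147) and HW_HN 1 (-0.075). Its nitrogen difference at sub-optimal water, 0.245, ran from -0.308 (without LW_HN 9) to 0.648 (without LW_HN 7) and was -0.308 without HW_HN 1 and LW_HN 9. The cause was not tested for any of these changes. Depth limits genes near the floor, where 3 reads per library came to between 0.0969 and 0.526 FPKM in the groups without reads.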

Other observations

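The averaged differences, the spread of lists between bulbs and the tests on genes that were on in some bulbs and off in others were all chosen only after the data were seen.

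The genes here are among those with the highest mean FPKM of all described genes, and no test was made of the kinds they belong to. Over the 12 bulbs g175051, similar to the class IV heat shock protein HSP22.7, averaged 7042 ± 4906 FPKM (SD) and ran from 2491 to 19409. The class I heat shock gene g243188, similar to HSP18.2, averaged 5673 ± 2749. A chitin recognition protein gene, g156425, ran from 523 to 20543 FPKM around a mean of 6356, and g317198, similar to pathogenesis-related protein PR-4A, from 186 to 11406 around 3293. The gene g463237, similar to translationally-controlled tumor protein, averaged 4905 ± 1454. Galactinol synthase, which starts the raffinose sugars that protect dry or heated tissue, was represented by g278890 at 4763 ± 1860. The aquaporin-like g345607 (PIP1-2) stood at 3918 ± 1513, the Peroxidase 42-like g55222 at 3536 ± 1621 and the lipid-transfer gene g177176, similar to AZI1, at 4421 ± 1589 FPKM.

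The means of most lists, those of other tissues included, spread more between bulbs of a group than those of random lists of the same size and expression. The random lists were not matched for the variance of single genes, so noisier genes raise the spread as well as genes that vary together. The SD of a list's mean between bulbs of a group was 0.74 on the log2 scale for flavonoid and anthocyanin synthesis, 0.50 for WRKY factors, 0.48 for class III peroxidases, 0.47 for jasmonate and lipoxygenase and 0.44 for phenylpropanoid and lignin genes. The random lists had 95th percentiles of 0.16, 0.17, 0.16, 0.11 and 0.11 (1000 lists each). Markers of photosynthetic cells followed at 0.40 against a 95th percentile of 0.12, and markers of dividing cells had 0.25 against 0.06. In all, 29 of 33 lists lay above that percentile. The other 4 were abscisic acid (0.13), dehydrins and LEA proteins (0.09), fructan and sucrose metabolism (0.08) and organelle proteins (0.06).

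With nitrogen averaged over both water regimes, 1 gene passed limma's threshold. This was the ALE2-like g427471, higher at sub-optimal nitrogen by 2.59 on the log2 scale (SE 0.27, adjusted p = 0.0164) and above 0 in all 6 bulbs of sub-optimal nitrogen and 1 of 6 of optimal nitrogen. With water averaged over both nitrogen regimes, 2 undescribed genes were lower at sub-optimal water, g292339 with a difference of -2.32 and g168347 with -3.35 (SE 0.24 and 0.35, adjusted p = 0.00755 for both). Both were lower in all 6 bulbs of sub-optimal water than in each bulb of optimal water. Chance cannot be excluded for either count. As many genes or more came from 28 of 100 groupings for nitrogen, with a highest other count of 1613, and from 5 of 100 for water, with a highest other count of 12. Unadjusted p-values under 0.05 numbered 1166 and 1359, and voom called 0 genes for both. Leaving out 1 library gave 0 to 7 genes for nitrogen and 2 to 9 for water, both highest without LW_HN 7. The nitrogen count was 0 without HW_HN 2, any 1 of the 3 HW_LN or any 1 of the 3 LW_LN libraries, without a filter and with the filter of 5 FPKM. The water count was 0 without HW_HN 1 and LW_HN 9 together. With a pseudocount of 0.1 neither g427471 nor g292339 was called.

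A set of 273 gene models had at least 3 FPKM in some bulbs and at most 0.3 FPKM in all others, in 99 patterns over the 12 bulbs, of which that of g149478 was uniform within the 4 groups. Of pairs under 100 kb apart, 61 of 61 shared a pattern, and fragments of one gene cannot be told apart from separate genes there, because only 4 such pairs had descriptions on both models (100% of these differed). Pairs at least 100 kb apart on one sequence shared a pattern 7.97 times as often as pairs on different sequences (14.1% against 1.77%). Up to 10 Mb apart, 22 of 34 such pairs shared one. All of these lay among models at 58367059 to 65578501 of chromosome 8, which had the same pattern, except the pair g83566 and g83599 on Scaffold_36052-HRSCAF_367672. Over 10 Mb apart, 16 of 235 shared one (6.81%). The ratio therefore leans on the chromosome 8 stretch and cannot decide whether split gene models are the whole cause elsewhere. With models closer than 100 kb counted as 1 block, 15 block pairs lay 100 kb to 10 Mb apart, on 5 sequences. Of these, 7 shared a pattern, against a mean of 0.293 when patterns were shuffled (permutation p = 1e-04, the smallest that 10000 shuffles can give). The sharing pairs lay only in the same chromosome 8 stretch and on Scaffold_36052-HRSCAF_367672, so at these distances they show no pattern spread over the genome. Patterns did recur farther apart, which was not tested by shuffling. On chromosome 5, g421129, g99440 and g107332 were on in HW_HN 2, HW_HN 3, HW_LN 4 and HW_LN 5 alone. They start at 47859410, 91219879 and 190598743. The same pattern held for g47123 and g49783 on scaffolds. The chromosome 8 pattern recurred in g170607 on Scaffold_46996-HRSCAF_430082. A candidate explanation, offered as a hypothesis that rests mainly on the chromosome 8 stretch, is that bulbs of the variety carried different inherited segments. Some differences between groups of 3 bulbs may then follow the bulbs' genotypes. Regional control of transcription was not tested and stays open.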
